A study of Escherichia coli K-12 with 2 samples.

How the data were processed

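The series holds 2 RNA-seq libraries of Escherichia coli K-12 MG1655, 1 from a strain that made the small RNA RprA carrying the MS2 aptamer (the MS2-RprA library) and 1 from a strain that made RprA without the aptamer (the RprA library, the background of the purification). Both strains lacked the chromosomal rprA gene and carried rne131, a truncation of RNase E that removes the part on which the RNA degradosome assembles. Per the labels' protocols, arabinose induced either form of RprA briefly in cells described as stationary phase, the cleared lysate was passed over amylose resin that held an MS2 coat protein fusion, and bound RNA was eluted with maltose, treated with DNase and made into libraries with a ScriptSeq kit.

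The authors deposited 1 table with 7632 rows, of which 4375 name a gene and 3257 name the interval between a pair of genes. Per the file headers, it gives for each row the read count of each library, the same count in a normalized form and the ratio of the normalized values. Reads were aligned with Bowtie, per the submitters' processing notes. Its version, the genome build, the annotation, the counting tool and the use of strand are not given in the sources used here. The deposited counts are whole numbers with no value below 1 in either library. The authors' normalized values equal the count divided by 1 constant per library, 4229540 for MS2-RprA and 4646905 for RprA, and their ratio equals the quotient of those values to within rounding (largest difference 0.0506). What the constants count is not stated. The listed rows sum to 15.2% of the constant in MS2-RprA and to 0.705% in RprA.

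Because no 0 is listed, a listed 1 may stand for no read. In the RprA library 3745 of the gene rows (85.6%) are at 1, against 119 (2.72%) in the MS2-RprA library. No pseudocount was added. In the report, a ratio with a control count of 1 to 3 is given with its counting interval, or with a statement that the interval held 1. Where the control count is 1, the ratio is the MS2-RprA count divided by the scale factor of 20.0, so it orders genes by their MS2-RprA count. This holds for 1688 (74.9%) of the genes that pass the depth filter.

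From the deposited counts, each count was divided by the library's total over gene rows (540185 reads in MS2-RprA, 27075 in RprA), and the ratio is MS2-RprA over RprA. Genes with 20 or more reads in the 2 libraries together passed the depth filter (2253 genes), and a gene was called higher or lower at a ratio of 4 in either direction. Each ratio has a 95% Clopper-Pearson interval of the 2 counts converted to a ratio. These intervals, and those of the shares, cover counting error only, since reads amplified without molecular identifiers are not independent molecules and 1 library per group leaves the spread between cultures unmeasured. With 1 library per group no test across samples was possible, no p-value is given, and no difference has a replicate check. Verbs of change are therefore avoided: a gene stood higher or lower in 1 of the 2 libraries.

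There were 20 gene lists fixed before the data were examined. For each list, the members that pass the filter were counted as at least 2-fold higher, at least 2-fold lower or between. The median log2 ratio of each list is given relative to the median of all passing genes (0.85 on the log2 scale, a ratio of 1.80), which removes the choice of scaling. It was placed as a percentile among 10000 random lists of the same size drawn from 20 bins of mean abundance, as a description of these libraries. Where the control count is 1, abundance and ratio both follow the MS2-RprA count, so matching compares such genes with others of nearly the same ratio and can hide a raised list. Percentiles without matching, and among genes with a control count of 2 or more, are therefore alternatives. The latter split is by the denominator of the ratio and leaves out genes that pass the filter with 1 control read, whose ratio is never below 0.952 (that of ydaM, 19 against 1), so it describes the members left and not the whole list. Genes named in the text follow a rule fixed at the same time: rprA, every published RprA target on the list, the 15 highest and 8 lowest ratios, the 5 most abundant genes of each library, and the 2 highest and 2 lowest passing members of each list. Operon neighbours may be named as such. Intergenic intervals, and any other gene, are named only where stated to be chosen after their values were seen.

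Gene names are those of the deposited table. Of its gene names, 4350 matched the RefSeq gene table of assembly ASM584v2, which was used for synonyms and for which genes neighbour each other. No coordinates are printed, because the authors' build is not stated. Copies of rRNA genes, of leucine tRNA genes and of insertion sequences share reads, and how the authors assigned such reads is not stated, so single copies are uncertain. Overlapping and antisense genes are uncertain for the same reason.

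The ratio and interval procedures were tested on 100 simulated pairs of libraries of 4375 genes. These were drawn with Poisson error from the real means, with 200 genes changed by known folds. At the scale the pairs were drawn with, 92.0% of genes raised 8-fold and 100% of those raised 32-fold were called higher, and the intervals held the true ratio for 98.1% of unchanged passing genes. Of genes lowered 8-fold, 17.0% were called lower, since most then fell under the depth filter. Scaled by gene-row totals, as the real pair is, 56.9% of genes raised 8-fold and 99.9% of those raised 32-fold were called. The raised genes had enlarged the MS2-RprA total 2.05-fold, the intervals held the true ratio for 80.4% of unchanged genes, and on average 153 unchanged genes were called lower. Total-count scaling thus pulls ratios down when many reads are gained by raised genes. A list raised in simulated values fell at percentile 100, and 50 unchanged lists averaged 51.1.

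Alternatives were TMM factors, the median ratio set to 1, totals without rRNA and tRNA or without rprA, a pseudocount of 5, no filter, a filter of 100, the authors' ratio, a 2-fold rule and the nearer bound of the interval. Others were chosen after seeing the data: a pseudocount of 0.5, 1 taken off every count with 0.5 added, control counts under 3 set to 3, control counts of 2 or more only, totals that include intergenic intervals, list percentiles without matching on abundance, and a listed 1 counted as 0 for shares of RNA classes. Their effect is given in the closing section. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 for the TMM factors alone.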

Results

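RprA is a small regulatory RNA of Escherichia coli that pairs with mRNAs with the help of the RNA chaperone Hfq. The study asked which RNAs come off an affinity column together with MS2-tagged RprA. An MS2-RprA eluate and an eluate from cells with untagged RprA were each sequenced as 1 library, so no value below has a replicate. Gene rows held 540185 reads in the MS2-RprA library and 27075 in the RprA library, and intergenic intervals held another 103304 and 5686. The control was therefore shallow: its median gene had 1 read, the lowest value listed, against 19 in MS2-RprA. Ratios are MS2-RprA over RprA after division by the gene-row totals, with 95% counting intervals in parentheses that cover counting error only.

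The bait is given first because it bears on the labels. The rprA row held 6 reads in the MS2-RprA library and 1 in the RprA library, below the depth filter of 20 reads. Its ratio was 0.301 (0.036 to 13.8), so a difference was not detectable at this depth, and the row does not tell the 2 labels apart. In the authors' deposited table the ratio for rprA is 6.6, on a scale described below. How reads of the introduced RprA were assigned is not stated.

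Reads of the rpoS region stood far higher in the eluate of tagged RprA. rpoS, which encodes the stationary-phase sigma factor and is the best known mRNA activated by RprA, had 6956 reads against 5, a ratio of 69.7 (29.9 to 215). nlpD, the lipoprotein gene just upstream that contains the main rpoS promoter, had the highest ratio of all, with 10446 reads against 5 (105, 44.9 to 323). hdeD, a membrane protein gene of the acid fitness island, had 1506 reads against 1 (75.5, 13.5 to 2983). Together rpoS, nlpD and hdeD took 3.50% of gene-row reads in MS2-RprA (3.45 to 3.55%) and 0.041% in RprA (0.020 to 0.073%). These 3 genes were set together after their values were seen.

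The other 3 genes on the list of published RprA targets did not stand apart at this depth. csgD, the master regulator of curli, had 21 reads against 1 (1.05, 0.169 to 43.5), and ydaM, a diguanylate cyclase gene, had 19 against 1 (0.952, 0.151 to 39.6). yqaE, a small membrane protein gene, had 4 against 1 and was under the filter. Among the 4 passing targets, 2 were at least 2-fold higher and none was at least 2-fold lower. Of these only rpoS could have been, since the others had 1 control read. The list's median lay 2.25 log2 units above the median gene, at percentile 99.9 of matched random lists, and 0.348 above it with no filter. It rests on rpoS and hdeD. The list was written from general knowledge, and where this study contributed to that knowledge the list is not independent evidence.

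Of 2253 genes that passed the filter, 440 stood at least 4-fold higher in MS2-RprA, 25 at least 4-fold lower and 1788 between. The control count was 1 for 363 of the higher genes and 2 or more for 77. For 34 higher and 9 lower genes the whole counting interval lay beyond 4-fold. The interval excluded 1 for 353 genes on the higher side and 78 on the lower side. Higher genes were 94.6% of those called. The filter and the lowest listed value of 1 shape that share. The 1688 passing genes with 1 control read had ratios of at least 0.952, so none could be lower at a 4-fold or 2-fold rule. With no filter there were 440 higher and 646 lower (40.5% higher). At a 2-fold rule 45.8% of all passing genes were higher and 3.68% lower, the background for the counts of list members. With the median ratio set to 1 the numbers were 200 higher and 75 lower (72.7% higher), and a pseudocount of 5 gave 36 higher and 409 lower. That pseudocount was added to the raw counts of both libraries, so it weighs far more on the shallower control. By this construction the median ratio fell from 1.80 to 0.409. The 409 therefore do not show a balance toward lower genes. In the authors' deposited table, whose ratio is 21.9 times the ratio used here, 2242 of these genes were at least 4-fold higher and 0 at least 4-fold lower.

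**Figure D1:**
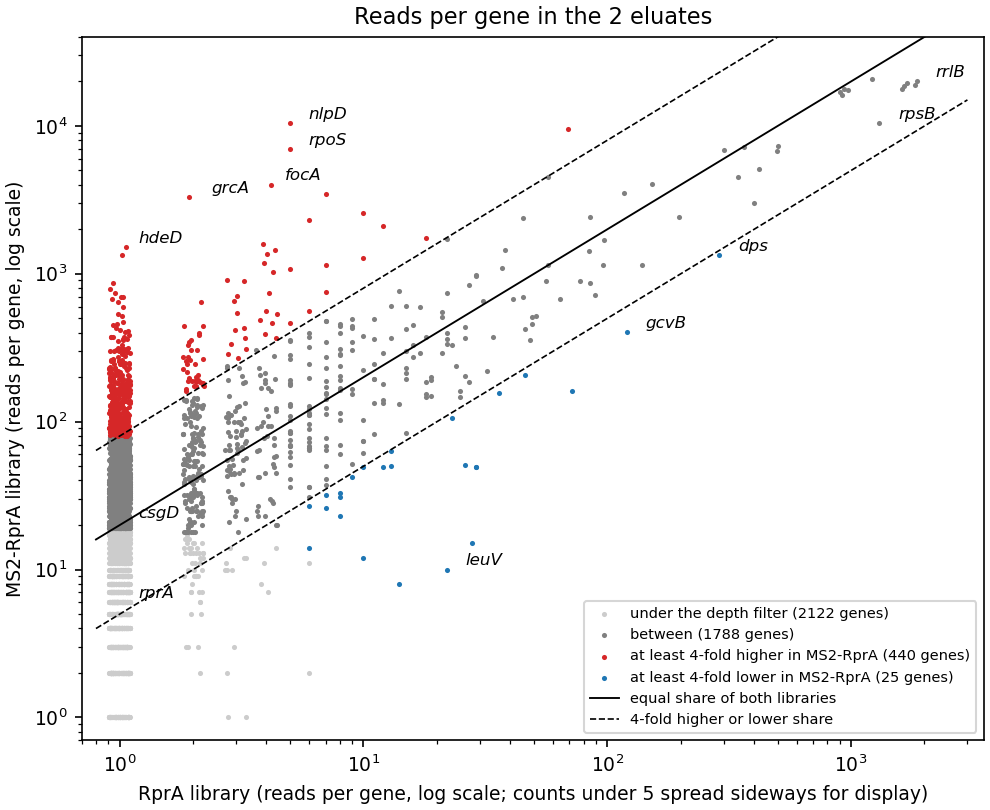
Reads per gene in the RprA library (x axis, log scale, counts under 5 spread sideways) and the MS2-RprA library (y axis, log scale), 1 point per gene row; the solid line marks equal shares of the gene-row totals and the dashed lines 4-fold differences. The 440 higher genes (red) lie mostly over a control count of 1, while rpoS (6956 against 5) and nlpD (10446 against 5) stand apart; on the authors' scale 0 genes are 4-fold lower, and of the 25 blue points 14 are at least 4-fold higher and 11 are not called.

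Among the 15 highest ratios were 4 genes linked to anaerobic metabolism, grouped after their values were seen. grcA, the spare glycyl radical protein of pyruvate formate-lyase, had 3282 reads against 2 (82.2, 22.8 to 679). focA, the formate channel gene, had 4009 against 4 (50.2, 19.6 to 184). The threonine dehydratase gene tdcB had 872 against 1 (43.7, 7.82 to 1728), and hemN, which encodes an oxygen-independent enzyme of haem synthesis, had 641 against 1 (32.1, 5.75 to 1271). No list of anaerobic genes was fixed beforehand. A later list left out these genes, the others that prompted it and any gene in the 80 rows first seen, those with the highest authors' ratios. It lay at percentile 14.9 of matched random lists and 56.8 without matching. Of its 39 passing members, 17 were at least 2-fold higher, against 45.8% of all passing genes. The random lists and that share kept the top genes that the list left out, which pulls the comparison down. The group as a whole was not shown to stand higher, and the question stays open.

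The remaining genes among the 15 highest each had 1 control read. wzzB, which sets O-antigen chain length, had 1347 reads in MS2-RprA and a ratio of 67.5 (12.1 to 2669). adk, the adenylate kinase gene, had 790 reads (39.6, 7.09 to 1566), and secB, an export chaperone gene, had 746 (37.4, 6.69 to 1479). lrhA, which encodes a repressor of flagellar genes, had 677 reads (33.9, 6.07 to 1342). The replication restart gene priB had 691 reads (34.6, 6.20 to 1370) and smg had 694 (34.8, 6.22 to 1376). ydcH had 598 reads (30.0, 5.36 to 1186). insH6, a transposase gene of an insertion sequence with several near-identical copies, had 533 reads (26.7, 4.77 to 1057) and is uncertain. For all of these the interval's lower bound was above 4. With control counts under 3 set to 3, 7 of the 15 highest genes stayed among the 15 highest.

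Outer membrane protein genes stood higher as a group. Of 17 passing members, 13 were at least 2-fold higher, 1 was at least 2-fold lower and 3 lay between. The list's median was 1.43 log2 units above the median gene, at percentile 98.9, or 95.7 among genes with a control count of 2 or more. pal, the peptidoglycan-associated lipoprotein gene, had 518 reads against 1 (26.0, 4.64 to 1027). The small porin gene ompW had 3456 against 7 (24.7, 12.0 to 61.6). At the other end, fepA, the enterobactin receptor gene, had 23 against 1 (1.15, 0.187 to 47.5). tolC, the outer membrane channel of efflux pumps, had 424 against 46 (0.462, 0.340 to 0.641), which on the authors' scale is 10.1 and thus above 1.

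Lists of envelope signalling, envelope stress and acid resistance stayed within the middle 95% of random lists matched on abundance. The Rcs phosphorelay, which controls the rprA promoter, and colanic acid genes had 6 passing members, 4 of them at least 2-fold higher, and lay at percentile 91.0. rcsB had 373 reads against 1 (18.7, 3.33 to 740) and rcsC 311 against 1 (15.6, 2.78 to 618), while ugd and yrfF each had 29 against 1 (1.45, 0.241 to 59.4). Envelope stress genes lay at percentile 84.1 (99.5 without matching), with 10 of 14 at least 2-fold higher. The protease gene degP had a ratio of 8.82 (1.56 to 350) and the chaperone gene skp 7.37 (1.30 to 293), while bamC stood at 1.10 and bamB at 1.03, with intervals that held 1. Acid resistance genes lay at percentile 89.4, with 10 of 20 at least 2-fold higher, near the 45.8% of all passing genes, and 0 at least 2-fold lower. Besides hdeD, the acid response regulator gene gadX had 181 reads against 1 (9.07, 1.61 to 360). adiC (1.00, 0.160 to 41.5) and gadC (0.927, 0.413 to 2.58) had the lowest ratios of that list.

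Arabinose genes, whose inducer both strains received, had 7 of 9 members at least 2-fold higher and lay at percentile 83.1, or 99.3 without matching on abundance. araJ had 2586 reads against 10 (13.0, 7.04 to 27.1) and araF 1032 against 4 (12.9, 5.04 to 47.6). The transporter genes araE (1.32, 0.858 to 2.16) and araG (0.996, 0.594 to 1.80) did not stand apart. Among 11 maltose genes, 8 were at least 2-fold higher, and the list lay at percentile 88.4. lamB, the maltoporin gene, had 356 reads against 1 (17.8, 3.18 to 707) and the activator gene malT 149 against 1 (7.47, 1.32 to 297). malZ (1.50) and malQ (0.842) had intervals that held 1.

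Genes for ribosomal proteins went both ways. Of 52 passing members, 34 were at least 2-fold higher and 1 was at least 2-fold lower, and the list lay at percentile 49.7, or 99.7 without matching on abundance. Their median ratio was 2.73, yet their pooled reads gave 0.690 (0.662 to 0.720), because a few abundant members stood low. Without rpsB and rplC the pooled ratio is 1.31 (1.21 to 1.42), and with them it is 15.1 on the authors' scale. rpsB had 10493 reads against 1304 (0.403, 0.381 to 0.428) and rplC 5076 against 421 (0.604, 0.547 to 0.669), ratios that are 8.8 and 13.2 in the authors' deposited table. rpsF (16.2, 4.48 to 134), which lies in an operon with priB, and rplI (12.3, 2.18 to 487) had the highest ratios. Genes of RNA decay and hfq itself lay at percentile 32, with 6 of 13 at least 2-fold higher, near the share of all passing genes. hfq had 428 reads against 3 (7.15, 2.43 to 34.8) and the enolase gene eno 138 against 1 (6.92, 1.22 to 275), while rnr (1.45) and csrA (0.535, 0.233 to 1.51) had intervals that held 1.

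Genes under the control of RpoS did not stand higher as a group. Of 27 passing RpoS-dependent genes, 11 were at least 2-fold higher, 5 at least 2-fold lower and 11 between. The median was -0.08 log2 units relative to the median gene, at percentile 8.16. The 10 members with a control count of 2 or more lay at percentile 0.145 of such genes, but that split is by the ratio's denominator and leaves out 17 members with ratios above 1.25, so it does not speak for the list. The pooled ratio of 0.420 (0.383 to 0.463) rests on dps and glgS, with 427 of the 489 control reads, and is 1.31 (1.01 to 1.71) without them. bolA had 170 reads against 1 (8.52, 1.51 to 339) and osmB 114 against 1 (5.71, 1.01 to 228), the latter falling to 0.994 with a pseudocount of 5. dps, the DNA-binding protein of starved cells, had 1341 against 288 (0.233, 0.205 to 0.266). yciE had 106 against 23 (0.231, 0.146 to 0.380). Both are 5.1 in the authors' deposited table.

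Curli, cellulose and cyclic-di-GMP genes lay at percentile 1.25, with a median of -0.78 log2 units relative to the median gene. Of 23 members, 15 were under the filter, 1 was at least 2-fold higher, 1 at least 2-fold lower and 6 between. gmr, a phosphodiesterase gene, had 153 reads against 1 (7.67, 1.36 to 305), and yedQ stood at 1.65 and bcsC at 0.468, with intervals that held 1. With a filter of 100 reads the list's median lay 0.50 log2 units above the median gene, since gmr was then its sole member. Flagellar and chemotaxis genes were mostly under the filter (38 of 44), and the 6 passing members lay at percentile 24.3. flhD (5.31) and flhC (4.66), the master regulator genes, had the highest ratios and fliC (1.30) and tsr (0.451) the lowest, and all 4 intervals held 1.

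Cold shock genes lay at percentile 6.50, with 5 of 13 at least 2-fold higher. infA stood at 9.37 (1.66 to 372) and ydfK at 6.52 (1.15 to 259). cspI (0.518) had an interval that held 1, and cspB had 41 reads against 7 (0.294, 0.130 to 0.776; 6.4 in the authors' deposited table). Heat shock genes lay at percentile 20.4, and their 7 members with a control count of 2 or more at 95.35 of such genes. The protease gene ftsH had 135 reads against 1 (6.77, 1.19 to 269), and clpB (2.93) and ibpA (0.752) had intervals that held 1. The small chaperone gene ibpB had 155 against 36 (0.216, 0.149 to 0.319; 4.7 in the authors' deposited table). Prophage and mobile element genes lay at percentile 65.2, with 3 of 13 at least 2-fold higher. gtrB (3.26) and gtrA (2.96) stood at the upper end and insC1 (1.10) and insD1 (0.351) at the lower, all with intervals that held 1.

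**Figure D2:**
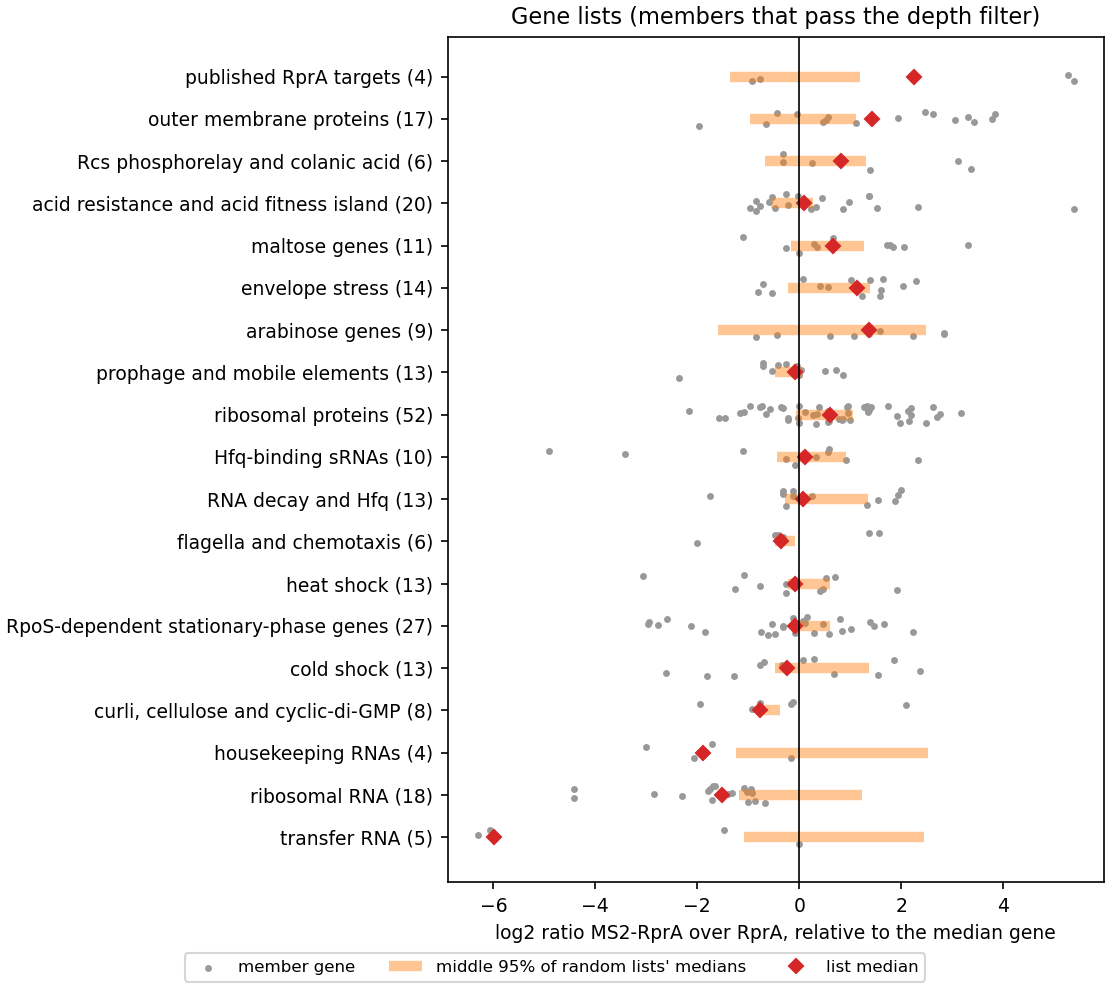
Log2 ratio of MS2-RprA over RprA relative to the median gene (x axis) for members that passed the depth filter (grey points, number in parentheses) and the median (red diamond) of each fixed list (y axis), ordered by percentile; the orange bar spans the middle 95% of medians of matched random lists. Published RprA targets (2.25) and outer membrane proteins (1.43) lie above their bars and rRNA (-1.52), housekeeping RNAs (-1.89) and tRNA (-5.98) below; with a pseudocount of 5 the rRNA median is 0.61, above the median gene, and housekeeping RNAs are at -0.46 and tRNA at -3.58 (-2.31 with no filter).

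Hfq-binding sRNAs did not stand higher as a class. Of the 27 listed, rprA among them, 17 were under the filter, 5 of the 10 others were at least 2-fold higher and 2 at least 2-fold lower, and the list lay at percentile 41.0. Its 4 members with a control count of 2 or more lay at percentile 1.85 of such genes, but that split leaves out 6 members with ratios of 1.50 to 9.02 and does not speak for the class. arrS, encoded beside hdeD, had 180 reads against 1 (9.02, 1.60 to 358), and omrB had 68 against 1 (3.41, 0.591 to 137). gcvB, which represses amino acid transporter genes, had 403 against 120 (0.168, 0.137 to 0.208; 3.7 in the authors' deposited table). fnrS, named after its value was seen, had 2385 against 45 (2.66, 1.98 to 3.65). ryfD had 12 against 10 (0.060, 0.024 to 0.155; 1.3 in the authors' deposited table). Pooled over the class, rprA included, the share was 0.631% in MS2-RprA (0.610 to 0.653%) and 0.750% in RprA (0.650 to 0.860%), a ratio of 0.842 (0.731 to 0.97) that is 1.02 with TMM factors and 18.5 on the authors' scale. That ratio rests largely on fnrS, with 2385 of the 3410 MS2-RprA reads of the class, and gcvB, with 120 of its 203 RprA reads; the 8 other passing members gave 1.21 (0.783 to 1.97).

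Stable RNAs took a smaller share of the MS2-RprA eluate. rRNA held 39.3% of gene-row reads in MS2-RprA (39.1 to 39.4%) and 56.6% in RprA (56.0 to 57.2%), a ratio of 0.694 that is 15.2 on the authors' scale. By subunit the ratio was 0.922 for 16S (1.12 with TMM factors), 0.565 for 23S and 0.117 for 5S rRNA (20.2, 12.4 and 2.56 on the authors' scale). tRNA held 0.081% against 0.598%, and housekeeping RNAs 0.070% against 0.236%, ratios of 0.136 and 0.298 that are 2.97 and 6.52 on the authors' scale. Counting a listed 1 as 0 changed the rRNA share in RprA to 65.6% and the tRNA share to 0.459%, since 55 of 72 tRNA rows had a control count of 1. All other gene rows held 60.0% against 41.8%, a ratio of 1.43 that is 0.794 with the median ratio set to 1.

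**Figure D3:**
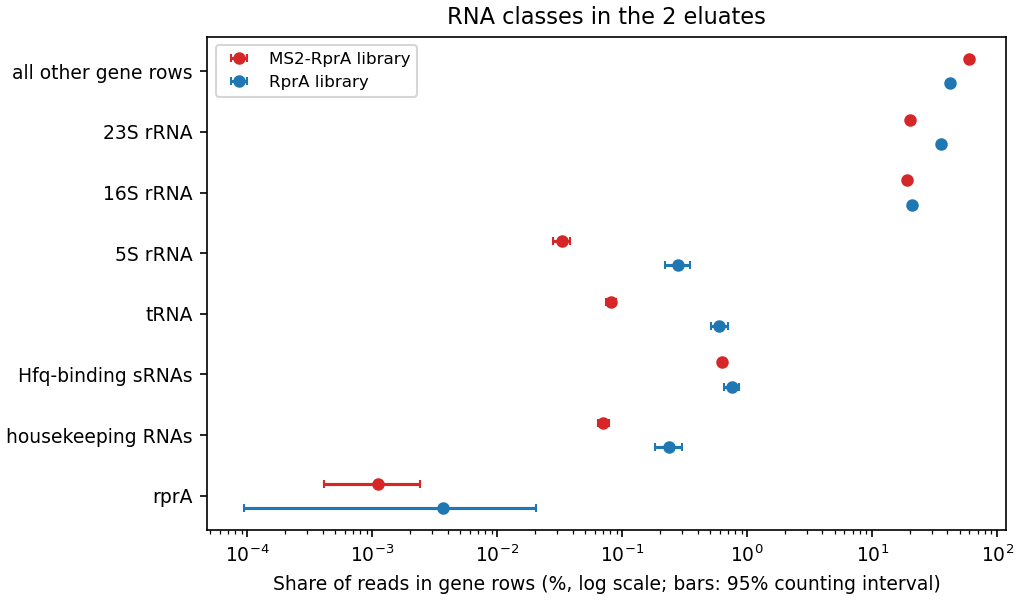
Share of gene-row reads (x axis, percent, log scale) taken by each RNA class (y axis) in the MS2-RprA library (red) and the RprA library (blue), 1 library each; bars are 95% Clopper-Pearson intervals and cover counting error only. tRNA (0.081% against 0.598%) and 5S rRNA (0.033% against 0.281%) lie furthest apart, and rprA, with 6 reads against 1, has overlapping intervals; on the authors' scale every class plotted has a ratio above 1.

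Within these classes the ratios varied between copies that share reads, so single copies are uncertain. The 5 most abundant genes were rrsC, rrlB, rrlC, rrlE and rrlA in MS2-RprA, and rrlB, rrlE, rrlC, rrlA and rrlH in RprA. rrsC had 20806 reads against 1217 (0.857, 0.809 to 0.909), which is 1.04 with TMM factors and 18.8 in the authors' deposited table. The 23S copies named here ran from rrlE at 0.523 to rrlC at 0.576, with rrlB at 0.538, rrlH at 0.550 and rrlA at 0.562. rrsD stood at 1.14 (1.02 to 1.28), below 1 with the median ratio set to 1, and rrsG at 0.985. The 5S copies rrfD and rrfF had identical counts, 49 against 29 (0.085, 0.052 to 0.139). Of the 18 passing rRNA copies 4 were at least 2-fold lower and none higher, and the list lay at percentile 0.26.

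Leucine tRNA copies had the lowest ratios of all passing genes. leuV had 10 reads against 22 (0.023, 0.010 to 0.050), leuQ 15 against 28 (0.027, 0.013 to 0.052) and leuP 8 against 14 (0.029, 0.010 to 0.073). These stay below 1 in the authors' deposited table, at 0.5, 0.6 and 0.6. The highest passing tRNA genes, serU (1.80) and ileV (0.652), had intervals that held 1, and 67 of 72 tRNA rows were under the filter. The 5 that passed lay at percentile 0, and leuV, leuQ and leuP passed the filter mainly through control reads. The list's median relative to the median gene, -5.98, was -2.31 with no filter and -3.58 with a pseudocount of 5. Among 4 passing housekeeping RNAs, at percentile 0.36 (5.50 among genes with a control count of 2 or more), ssrA, the tmRNA that rescues stalled ribosomes, had 206 reads against 46 (0.224, 0.162 to 0.316; 4.9 in the authors' deposited table). ssrS (0.432), rnpB (0.551) and csrB (1.60) had intervals that held 1. Outside these classes and the sRNAs, the 2 lowest genes were fsr, a fosmidomycin efflux gene, with 51 reads against 26 (0.098, 0.060 to 0.164) and yejL with 161 against 72 (0.112, 0.084 to 0.150). Both exceed 1 in the authors' deposited table, at 2.2 and 2.5.

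Many intergenic intervals beside the top genes stood high as well. Among 791 intervals that passed the filter, 127 were at least 4-fold higher and 11 at least 4-fold lower, and for 11 higher intervals the whole counting interval lay above 4-fold. The intervals named here were chosen after their values were seen. The interval between focA and ycaO had 1315 reads against 1 (65.9, 11.8 to 2605), and that between rpoS and nlpD had 3658 against 3 (61.1, 20.9 to 296). The intervals between grcA and ung (27.2, 4.86 to 1075) and between secB and grxC (26.9, 4.80 to 1063) were also among the 5 highest, as was that between bamD and raiA (33.6, 6.02 to 1330), which adjoins none of the 15 highest genes. Of 23 passing intervals beside those 15 genes, 16 had a counting interval above 1, 6 had one that held 1 and 1 had one below 1. Among the 6 were those between nlpD and pcm (1.50, 0.250 to 61.3), pflB and focA (1.58, 0.419 to 13.3) and htpG and adk (2.16, 0.367 to 87.1), and the lowest lay between hisI and wzzB (0.238, 0.079 to 0.962).

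Across genes, the 2 eluates resembled each other in part. The log2 counts of 2253 passing genes correlated with Pearson's r = 0.640 and Spearman's rho = 0.405. Over the 565 of them with a control count of 2 or more, r was 0.701 and rho 0.527. Genes are not independent replicates, so no p-value is attached.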

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

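With 1 library per group, depth limits these results: a control count of 1 sets the ratio of most passing genes. The alternatives named below with a pseudocount of 0.5, 1 taken off every count, control counts under 3 set to 3, control counts of 2 or more, intergenic intervals in the total, no matching on abundance, or a listed 1 counted as 0 were chosen after seeing the data. The rprA ratio ran from 0.092 (pseudocount 5) to 0.551 (1 taken off every count, 0.5 added), within its counting interval. The authors' ratio of 6.6 is on a scale 21.9 times larger, to which that interval does not apply. The median log2 ratio of passing genes moved by 0.28 with TMM factors, by -0.85 with the median ratio set to 1, by -0.50 with totals without rRNA and tRNA and by 4.46 with the authors' ratio. A scaling cannot reorder genes. Of the 15 highest, 14 were shared with a pseudocount of 0.5, 8 with a pseudocount of 5, 7 with control counts under 3 set to 3 and 4 with control counts of 2 or more.

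Against 440 genes at least 4-fold higher, there were 200 with the median ratio set to 1, 277 without rRNA and tRNA, 36 with a pseudocount of 5, 2242 with the authors' ratio, 1032 at a 2-fold rule, 34 by the interval's nearer bound, 273 with a pseudocount of 0.5, 948 with 1 taken off every count and 0.5 added, 120 with control counts under 3 set to 3 and 77 with control counts of 2 or more. Against 25 at least 4-fold lower, there were 15 with TMM factors, 75 with the median ratio set to 1, 46 without rRNA and tRNA, 409 with a pseudocount of 5, 646 with no filter, 6 with a filter of 100, 0 with the authors' ratio, 83 at a 2-fold rule and 9 by the nearer bound. A pseudocount or a missing filter acts on rows at the control's lowest value, as built.

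A scaling multiplies every ratio alike, so by construction it cannot move list medians relative to the median gene, apart from rounding of the authors' ratio. Under the 7 settings that can, 131 medians stayed within the 95% bootstrap interval of the list's median in 105 cases and moved beyond it in 24. That interval comes from resampling a list's passing members 10000 times and is narrower than the spread of single members. Of lists outside the middle 95% of matched random lists, 2 medians crossed 0; 17 medians of lists inside it did too. rRNA turned to 0.61 with a pseudocount of 5, and was -0.57 with no filter, -2.78 with a filter of 100, -2.46 with 1 taken off, -0.23 with control counts under 3 set to 3 and -0.82 with control counts of 2 or more. Curli genes turned to 0.50 with a filter of 100 and were -1.25 with control counts of 2 or more. With no filter, published targets were at 0.348, against 2.25, ribosomal proteins at 1.70, flagella at -1.46, Rcs at -2.04, cold shock at 0.89, heat shock at 0.96 and envelope stress at 1.61. With a filter of 100, housekeeping RNAs were at -4.59, ribosomal proteins at -0.65, heat shock at -1.36 and envelope stress at 0.013. With control counts of 2 or more, published targets were at 5.97 (rpoS alone), ribosomal proteins at 1.03, RpoS-dependent genes at -1.29, flagella at -1.30 and envelope stress at -0.022. Ribosomal proteins were at 1.30 with a pseudocount of 5 and 1.17 with control counts under 3 set to 3, and tRNA at -6.96 with 1 taken off. Within their bootstrap intervals, tRNA was at -2.31 with no filter and -3.58 with a pseudocount of 5. Housekeeping RNAs, also within theirs, were at -0.46 with a pseudocount of 5 and -0.61 with control counts under 3 set to 3. No tRNA and no prophage gene passed a filter of 100.

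Without matching on abundance, ribosomal proteins were at percentile 99.7, arabinose genes at 99.3 and envelope stress at 99.5, beyond the middle 95%. Keeping genes with a control count of 2 or more splits by the ratio's denominator. It drops only ratios of 0.952 and above, on both sides of the median gene's 1.80. Under that split, outer membrane proteins (95.7) and housekeeping RNAs (5.50) came inside the middle 95%. Hfq-binding sRNAs (1.85) and RpoS-dependent genes (0.145) lay below it, and heat shock was at 95.35 against 20.4, inside it. Published targets, curli, flagella and Rcs genes then had 1 member each and no percentile.

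Of named genes whose counting interval excluded 1, 24 values crossed 1, and 87 values did where the interval held 1. The authors' ratio was above 1 for rrsC (18.8), rplC (13.2), rrlC (12.6), rrlA (12.3), rrlH (12.1), rrlB (11.8), rrlE (11.5), tolC (10.1), rpsB (8.8), cspB (6.4), dps (5.1), yciE (5.1), ssrA (4.9), ibpB (4.7), gcvB (3.7), yejL (2.5), fsr (2.2), rrfD (1.9), rrfF (1.9) and ryfD (1.3), by the construction of its constants. rrsC was 1.04 with TMM factors. rrsD was 0.632 with the median ratio set to 1 and 0.805 without rRNA and tRNA, and osmB 0.994 with a pseudocount of 5. The correlation between the libraries was 0.528 with no filter and 0.701 with control counts of 2 or more. The share in RprA was 65.6% for rRNA and 0.459% for tRNA with a listed 1 counted as 0. Beyond the settings' own construction, the cause of these shifts was not tested.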

Other observations

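Neighbouring genes tended to have alike ratios. After the median of each abundance bin was removed, log2 ratios of genes next to each other correlated at r = 0.234 over 1469 pairs, above the highest of 1000 shuffles of the gene order (0.089). The correlation was 0.09 for genes 2 apart, -0.01 for genes 5 apart and 0.04 for genes 20 apart. Ratios that follow whole transcripts are a candidate explanation, as for nlpD beside rpoS. Reads that span or overlap a gene boundary would give the same correlation and were not separated from it. Neighbours of like abundance could give it too. For most passing genes the control count is the lowest listed, so the log2 ratio follows the MS2-RprA count. Removing a bin's median leaves abundance differences within the bin, and shuffling the gene order does not control for them. The correlation therefore cannot tell whether ratios follow transcripts.

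The number of anaerobic and sugar uptake genes among the highest ratios prompted a pair of hypotheses, each tested without the genes that prompted it or any gene in the 80 rows first seen. Anaerobic growth genes as a group may stand higher. Their 39 passing members lay at percentile 14.9 of matched random lists, with 17 at least 2-fold higher and 0 at least 2-fold lower, against 45.8% and 3.68% of all passing genes. aspA, the aspartase gene, had 2114 reads against 12 (8.83, 5.04 to 17.1). Sugar uptake genes lay at percentile 12.7, with 23 of 49 at least 2-fold higher and 3 at least 2-fold lower. The galactitol genes gatY (10.7, 4.58 to 33.1) and gatZ (8.20, 3.97 to 20.4) had high ratios, while the mannitol gene mtlD (0.321, 0.210 to 0.511) had a low one. Matching on abundance also matches the ratio of members with a control count of 1 (17 anaerobic and 26 sugar uptake genes), so these percentiles exclude nothing. Without matching they were 56.8 and 23.9. Over members with a control count of 2 or more (22 and 23 genes), a split by the ratio's denominator, they were 86.2 and 49.7 with matching and 92.9 and 59.7 without. The random lists and the shares of all passing genes kept the top genes that the tested lists left out, which pulls all of these percentiles down. Whether either group stands higher stays open. The genes named, and the percentiles other than the matched ones, were chosen after values were seen.

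Some genes of the reference are not listed in unbroken blocks. The longest holds 26 neighbouring genes, ending in mcrA and lying where the e14 prophage sits beside icd, against a longest run of 5 in 1000 shuffles, and no interval inside it is listed. Another of 24 genes runs from yahG to lacZ, and 1 of 7 genes from mhpR to mhpE. Chromosomal deletions in the strain may account for such blocks. How rows were chosen for the table is not stated, so other reasons stay open. This test, the tests of the rprA row and the test of the library constants were chosen after the values were seen.

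The 440 genes at least 4-fold higher were weighed against 2 technical explanations. Simulated pairs with no difference, drawn at the control's depth with values under 1 set to 1, gave at most 25 such genes in 100 pairs, and 0 whose counting interval lay at or above 4-fold, against 34 observed. A common shift of every gene, rRNA included, to the median ratio of 1.80 gave at most 117 and 0. Neither setting gave the number seen. The median ratio itself depends on how low control counts are handled: it was 3.46 with 1 taken off every count and 0.5 added, and 5.41 with a filter of 100. No larger shift was simulated, so a larger common shift stays open. Spread between library preparations, which 1 library per group cannot show, stays open, as does capture with tagged RprA.

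The rprA row held 6 reads in the library of its own tagged form. Complete loss of small RNAs is argued against by 5 of the 26 other listed Hfq-binding sRNAs having at least 10 times as many reads. A lower yield of short RNAs stays open, since their median was 11.5 reads and 7 had as few as rprA or fewer. Exchanged labels are argued against by 2 published targets, rpoS and hdeD, whose intervals lay above 1 in the library labelled MS2-RprA, with 0 below. With the 1 control read that hdeD, csgD, ydaM and yqaE had, no interval could lie below 1. The count of 0 below therefore rests on rpoS alone. Where this study contributed to the list of targets, the list cannot check the labels. Whether reads of the tagged RNA were left outside the rprA row cannot be told apart from a true shortage, because the listed rows hold 15.2% of the library constant and the rest is not listed.

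The authors' ratio exceeds 1 for nearly every row: its median is 12.1, and 7 rows of 7632 lie below 1. The library constants may count reads that lie outside the listed rows, and rRNA was predicted to be raised about as much as other rows in that case. The pooled rRNA ratio on that scale was 15.2, within 2-fold of the median row. It was more than 2-fold below the median passing gene (39.6) and all other gene rows pooled (31.4). A constant acts on all rows of its library alike, so it cannot change how rRNA stands to other rows. The comparison therefore cannot tell what the constants count. More RNA of every kind in the MS2-RprA eluate could give such values too, so which of the 2 scales, 21.9-fold apart, is nearer the truth stays open.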
